A study of Mus musculus with 48 samples.

How the data were processed

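RNA was measured in NMM, a mouse melanoma cell line with a mutated NRAS gene, by stranded sequencing of poly(A) RNA. The 48 libraries comprised 12 groups, unstimulated cells and 11 cytokine conditions, each with 1 library at 2, 6, 12 and 24 h. The 4 libraries of a group are durations and not replicates, and the labels do not say whether they came from separate cultures. The doses were taken from the sample titles and stimulus labels, because separate dose fields read 1 where the titles give 0.1 ng/ml TNF or 0.01 ng/ml IFNγ. The protocol also describes supernatant from co-cultures, which was not analysed here.

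The deposited values are raw read counts per Ensembl gene for 49671 genes, with no normalisation. Per the labels, the authors aligned reads with HISAT to the mouse genome build GRCm38. The HISAT version, the counting tool, the annotation release and the strand setting of the counting are not given in the sources used here. Of the 49671 genes, 49412 were found in the annotation used here as a check and 45214 had the same start and end there. Genes that overlap on opposite strands, and paralogs such as the Gbp, Irgm-related, H2, Oas, Ifit, Apol and Serpina3 families, may hold reads of one another, and genes with processed pseudogenes such as Gapdh may have lost reads.

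Counts were analysed in R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0. The edgeR filter for low counts (minimum count 10, minimum total 15) left 12203 genes, normalised with TMM factors. A quasi-likelihood model with robust dispersion held 1 term per stimulus and 1 per duration over all 48 libraries, with 33 residual degrees of freedom. Each stimulus effect is therefore a mean over the 4 durations. Its test takes as spread how much the differences between stimuli vary over the durations. This spread is pooled over all groups. A stimulus with little effect is thus judged partly by the time courses of strong ones, and a strong one partly by those of weak ones. Counts with the compared groups alone, which do not pool in this way, are given as well. Duration is paired across stimuli by the duration term. A second model added, for each stimulus, a slope on log2 of the hours and had 22 residual degrees of freedom. Calls are genes with a Benjamini-Hochberg adjusted p under 0.05 within a comparison, and all tests are two-sided. Errors given with ± are standard deviations where so named. All others are the absolute log2 change divided by the square root of the F statistic of its test. They are approximate standard errors and were not taken from the fitted coefficients. Values at single durations are log2 ratios of CPM (counts scaled to a common library total) with a prior count of 2, among genes with at least 5 CPM in either library, and carry no test.

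The comparisons, the gene lists and the rule for naming genes were fixed before the data were examined. The rule took, per comparison, the 10 largest increases and decreases among called genes with an absolute log2 change of at least 1 and the same sign at all 4 durations, without predicted genes. For slopes and non-additivity it took the 10 largest called changes each way. Any list member could also be named. Which of these genes are printed was decided after their values were seen, with preference for genes whose call held when any 1 duration was left out.

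The 23 lists were type II and type I interferon responses, interferon-inducible GTPases, MHC class I and class II presentation, NF-κB feedback and pathway, chemokines and cytokines, T cell ligands with adhesion and checkpoint genes, cell death, TGF-β and SMAD targets, melanocyte lineage, dedifferentiation, cell cycle, immediate early genes, hypoxia and glycolysis, cholesterol biosynthesis, the integrated stress response with amino acid supply, the unfolded protein response, cytokine receptors and signalling, and markers of T and NK cells, macrophages, fibroblasts and endothelium. Some genes stand in more than 1 list. The 20 lists with at least 5 tested members were tested with camera at the preset correlation of 0.01, adjusted over 460 pairs of list and comparison. Of these pairs, 210 were called, and 70 with a correlation estimated from the data. The adjusted p with an estimated correlation is given wherever that call was lost.

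Libraries held 5612907 to 9663207 counts, so that 1 count was worth 0.103 to 0.178 CPM. Where the reference group had 0 counts over its 4 libraries, the ratio was taken against a floor of 3 counts over the group and given as a lower bound. With 1 to 3 counts, the ratio is given with its 95% interval, from an exact binomial (Clopper-Pearson) interval. The 95% Wilson interval of a library's share of counts reached at most 0.00906 percentage points to either side for the mitochondrial share and 0.0266 for the 50 highest genes. Such bounds and intervals cover counting error only. The labels carry 24 different index sequences: the libraries of 2 h and 6 h use all 24, and those of 12 h and 24 h use the same 24 again. The 2 sets were therefore handled as possible batches, and counts within each are given beside the pooled ones.

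Alternatives were DESeq2 size factors, no filter, the DESeq2 Wald test, no duration term, IL-2 libraries as the reference, the compared groups alone, each duration left out in turn, hours on a linear scale, an estimated correlation, a prior count of 0.5 and a log2 limit of 2. The counts within the 2 index sets and the further pairs of durations were added after seeing the data. The model was tested on simulated data: for IL-2 against unstimulated cells, 51 of 64 genes simulated with a log2 change of 1 and 8 of 11701 unchanged genes were called. For non-additivity these were 50 of 66 and 10 of 11695. Apart from the genes changed on purpose, the simulated libraries had no effect of stimulus, duration or batch, and genes varied independently. The few false calls therefore do not show the error rate in the real data.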

Results

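NMM cells, a mouse melanoma line with mutated NRAS, were left unstimulated or given 1 of 11 cytokine conditions. The series title names cytokines derived from CD8+ T cells in tumours, and the comparisons ask which transcripts of the tumour cells each cytokine changed, at which dose, alone or together, and over time. IFNγ was given at 0.01, 1 and 100 ng/ml and TNF at 0.1, 1 and 10 ng/ml. Both were given together at 100 and 10 ng/ml, called the combination here. The remaining conditions were IFNα1 at 5000 U/ml, TGF-β at 10 ng/ml, lymphotoxin α1β2 at 2 ng/ml and IL-2 at 6000 U/ml. Each condition had 4 libraries, 1 each at 2, 6, 12 and 24 h, with 5612907 to 9663207 counts per library. Changes are log2 ratios of means over the 4 durations, and there are no replicates at any single duration. The first component of the log2 CPM values held 33.9% of the variance and the second 18.3%.

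**Figure D1:**
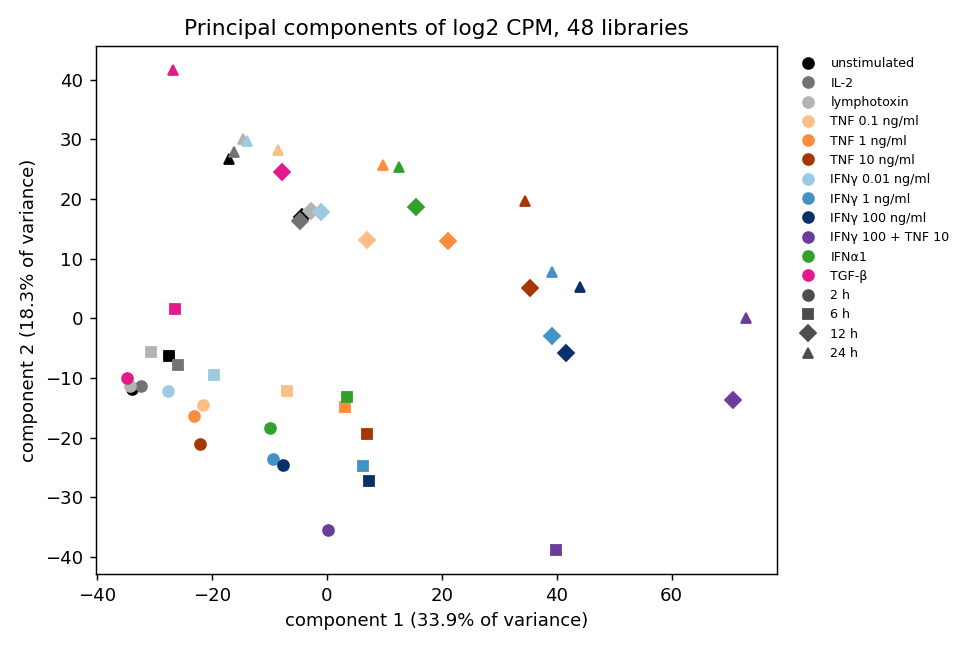
Position of the 48 libraries on the first and the second principal component of log2 CPM, which held 33.9% and 18.3% of the variance. Colours are stimuli and marker shapes are durations (2, 6, 12 and 24 h), and each point is 1 library.

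IFNγ at 100 ng/ml was compared with unstimulated cells to ask which transcripts it changed. All 23 tested genes of the type II interferon list rose, with a median log2 change of 2.94 (adjusted p = 2.52e-41). Among them were Irf1, a transcription factor of the interferon response (3.89 ± 0.31, adjusted p = 1.8e-11), and Cxcl9, a chemokine that attracts T cells (8.19 ± 0.75, from 6 to 1890 counts over the 4 libraries, chromosome 5, 92321347 to 92328079 in GRCm38). All 19 interferon-inducible GTPases rose (median 2.84, adjusted p = 7.67e-56), with Gbp10 higher by 7.25 ± 0.46 and Gbp2 by 3.94 ± 0.36. Of 24 genes of MHC class I presentation, 21 rose (median 1.64, adjusted p = 5.10e-27), including the transactivator Nlrc5 (2.21 ± 0.26), the immunoproteasome subunit Psmb9 (2.84 ± 0.29) and the peptide transporter Tap1 (1.81 ± 0.23). Cd274, which encodes the checkpoint ligand PD-L1, rose by 3.62 ± 0.45. It was 1 of 10 among 17 tested genes for T cell ligands, adhesion and checkpoints that rose (median 1.10, or 0.69 with members near the floor at their bound, adjusted p = 8.52e-06). Among 33 cell death genes, 20 rose and 2 fell (adjusted p = 5.10e-12), with the inflammatory caspase Casp4 higher by 2.62 ± 0.31 and Casp1 by 1.98 ± 0.25. Socs1 and Socs3, feedback inhibitors of cytokine signalling, rose by 1.66 ± 0.27 and 2.09 ± 0.16. Serpina3f and Ido1, an enzyme that degrades tryptophan, had no counts in unstimulated cells and were at least 63.9-fold and 10.7-fold higher. Ciita, the transactivator of MHC class II, stood at 48 counts against 2 (24.1-fold, 95% interval 6.32 to 205). It was the 1 called gene of the 5 tested on the MHC class II list (median -0.15 and mean 0.90, adjusted p = 0.789). Lower genes included Cxcr4, a chemokine receptor (-1.47 ± 0.29), and Tert, the telomerase subunit (-1.47 ± 0.33).

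With IFNγ at 100 ng/ml, 2702 of 12203 genes were called, 1567 higher and 1135 lower, and 1402 of the higher and 972 of the lower ones had the same sign at all 4 durations. Of the called genes, 389 were at least 2-fold higher and 62 at least 2-fold lower. The calls of the type II interferon, GTPase, MHC class I, checkpoint and cell death lists held with an estimated correlation. Adjusted over the list alone, the counts were the same except for 11 higher and 1 lower checkpoint genes and 1 lower MHC class II gene. The type I interferon list had 34 of 38 genes higher (35 adjusted over the list alone, median 0.95, adjusted p = 1.01e-22), and its call was lost at adjusted p = 0.138 with an estimated correlation. Among the 2 h and 6 h libraries alone, Cxcr4 (-0.60, adjusted p = 0.42) and Tert (-1.16, adjusted p = 0.224) were not called, nor was Cxcr4 without a duration term (-1.61). The count was 1577, 1041 and 1777 without the 6 h, 12 h and 24 h libraries (521, 232 and 636 of them lower). It was 446 (82 lower) within the 2 h and 6 h libraries, 3402 (1592 lower) within the 12 h and 24 h ones and 1474 (481 lower) with the compared groups alone. The mitochondrial share of counts, which can follow RNA quality, was 0.693% at 24 h with this dose, 0.964% in unstimulated cells and 0.851% with IL-2.

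TNF at 10 ng/ml was compared with unstimulated cells in the same way. Of 34 genes of the NF-κB list, 25 rose (30 adjusted over the list alone, with 1 lower, median 0.92, adjusted p = 3.41e-43), among them the feedback inhibitors Nfkbia (2.68 ± 0.20, adjusted p = 4.78e-12) and Tnfaip3 (2.12 ± 0.18) and the apoptosis inhibitor Birc3 (2.43 ± 0.21). Of 27 chemokines and cytokines, 18 rose (19 adjusted over the list alone, with 1 lower, median 2.36, adjusted p = 5.67e-17), including the monocyte chemokine Ccl2 (5.12 ± 0.54) and the neutrophil chemokine Cxcl1 (3.76 ± 0.44). Cxcl2, with no counts in unstimulated cells, was at least 32.3-fold higher. The adhesion molecule Vcam1 rose by 3.83 ± 0.41, the signalling adaptor Traf1 by 5.34 ± 0.58 and Acod1, the enzyme that makes itaconate, by 6.35 ± 0.69. Interferon-stimulated genes were higher too: 16 of 23 type II genes (17 adjusted over the list alone, median 1.17), 17 of 19 GTPases (18, median 1.17), 20 of 24 MHC class I genes (21, median 0.96) and 30 of 38 type I genes (35, median 0.76). The 4 tests gave adjusted p = 5.24e-14, 1.22e-13, 1.95e-14 and 3.72e-17, and with an estimated correlation adjusted p = 0.0321, 0.123, 0.118 and 0.232, at which the last 3 calls were lost. The type I median stood at 0.14 at 2 h and 0.94 at 6 h, without a test of that step. Lower genes included Mrgprf, an orphan receptor (-2.78 ± 0.58), Atoh8, a transcription factor (-2.39 ± 0.38), and Bmf, which promotes apoptosis (-1.87 ± 0.33).

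With TNF at 10 ng/ml, 2091 genes were called, 1200 higher and 891 lower, with the same sign at all 4 durations for 1084 and 824. Of the called genes, 316 were at least 2-fold higher and 91 at least 2-fold lower. The calls of the NF-κB and chemokine lists held with an estimated correlation. Mrgprf was not called among the 2 h and 6 h libraries alone (-2.17), nor Atoh8 (-2.39) and Bmf (-1.82) without a duration term. The count was 920, 794 and 1122 without the 6 h, 12 h and 24 h libraries (274, 222 and 397 of them lower). It was 283 (73 lower) within the 2 h and 6 h libraries and 2398 (1076 lower) within the 12 h and 24 h ones.

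The combination of IFNγ and TNF was compared with unstimulated cells and with each cytokine alone, to ask what joint exposure adds. Against unstimulated cells, Cxcl9 rose by 12.63 ± 0.63 (from 6 to 42071 counts), the adhesion molecule Icam1 by 7.24 ± 0.48, the death receptor Fas by 4.33 ± 0.35 and Cd274 by 4.51 ± 0.46. Nos2, the inducible nitric oxide synthase (chromosome 11, 78920787 to 78960254), had no counts in unstimulated cells and 680 in the combination, at least 212-fold more. Serpina3f was at least 790-fold higher and Cxcl2 at least 49.0-fold. All 23 type II genes (median 3.44), all 19 GTPases (3.06), 31 of 34 NF-κB genes (33 adjusted over the list alone, 1.34) and 21 of 24 MHC class I genes (2.05) rose (adjusted p = 4.04e-32, 4.04e-32, 8.99e-34 and 9.76e-23). Of 33 cell death genes, 22 rose and 3 fell (24 and 3 adjusted over the list alone, adjusted p = 2.06e-14), with Casp4 and the pore-forming Gsdmd higher by 4.14 ± 0.30 and 2.98 ± 0.30 and the apoptosis inhibitor Bcl2 lower (-1.12 ± 0.17). Among 29 genes of the integrated stress response and amino acid supply, 25 rose (26 adjusted over the list alone, median 0.63, adjusted p = 1.26e-08, or adjusted p = 0.3 with an estimated correlation), including the kinase-like regulator Trib3 (1.44 ± 0.22), the transcription factor Atf4 (0.70 ± 0.10) and the cystine transporter Slc7a11 (1.15 ± 0.18). Of 22 genes of cholesterol biosynthesis, 19 fell (20 adjusted over the list alone, median -0.61, adjusted p = 1.53e-07, or adjusted p = 0.306 with an estimated correlation), among them Mvd (-1.16 ± 0.23). Other lower genes were Trib2, a kinase-like regulator (-2.49 ± 0.23), and Bmf (-2.99 ± 0.37).

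Against unstimulated cells, 5129 genes were called with the combination, 2546 higher and 2583 lower, with the same sign at all 4 durations for 2002 and 1965. Of the called genes, 769 were at least 2-fold higher and 317 at least 2-fold lower, so that most calls were smaller changes. With DESeq2 size factors 2645 were higher and 2434 lower. Without the 2 h, 6 h, 12 h and 24 h libraries 2862, 2165, 1914 and 2027 were higher and 2839, 1775, 1522 and 1574 lower, so that the balance turned in each of these 5 settings. The count was 2024 (723 lower) with the compared groups alone, 1853 (598 lower) within the 2 h and 6 h libraries and 5355 (2596 lower) within the 12 h and 24 h ones. The calls of the type II, GTPase, NF-κB, MHC class I and cell death lists held with an estimated correlation, and those of the stress and cholesterol lists were lost. Mvd was not called with the compared groups alone, at -1.24, nor among the 2 h and 6 h libraries, at -0.45. The mitochondrial share of counts was 0.513% at 24 h with the combination, 0.964% in unstimulated cells and 0.851% with IL-2.

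**Figure D2:**
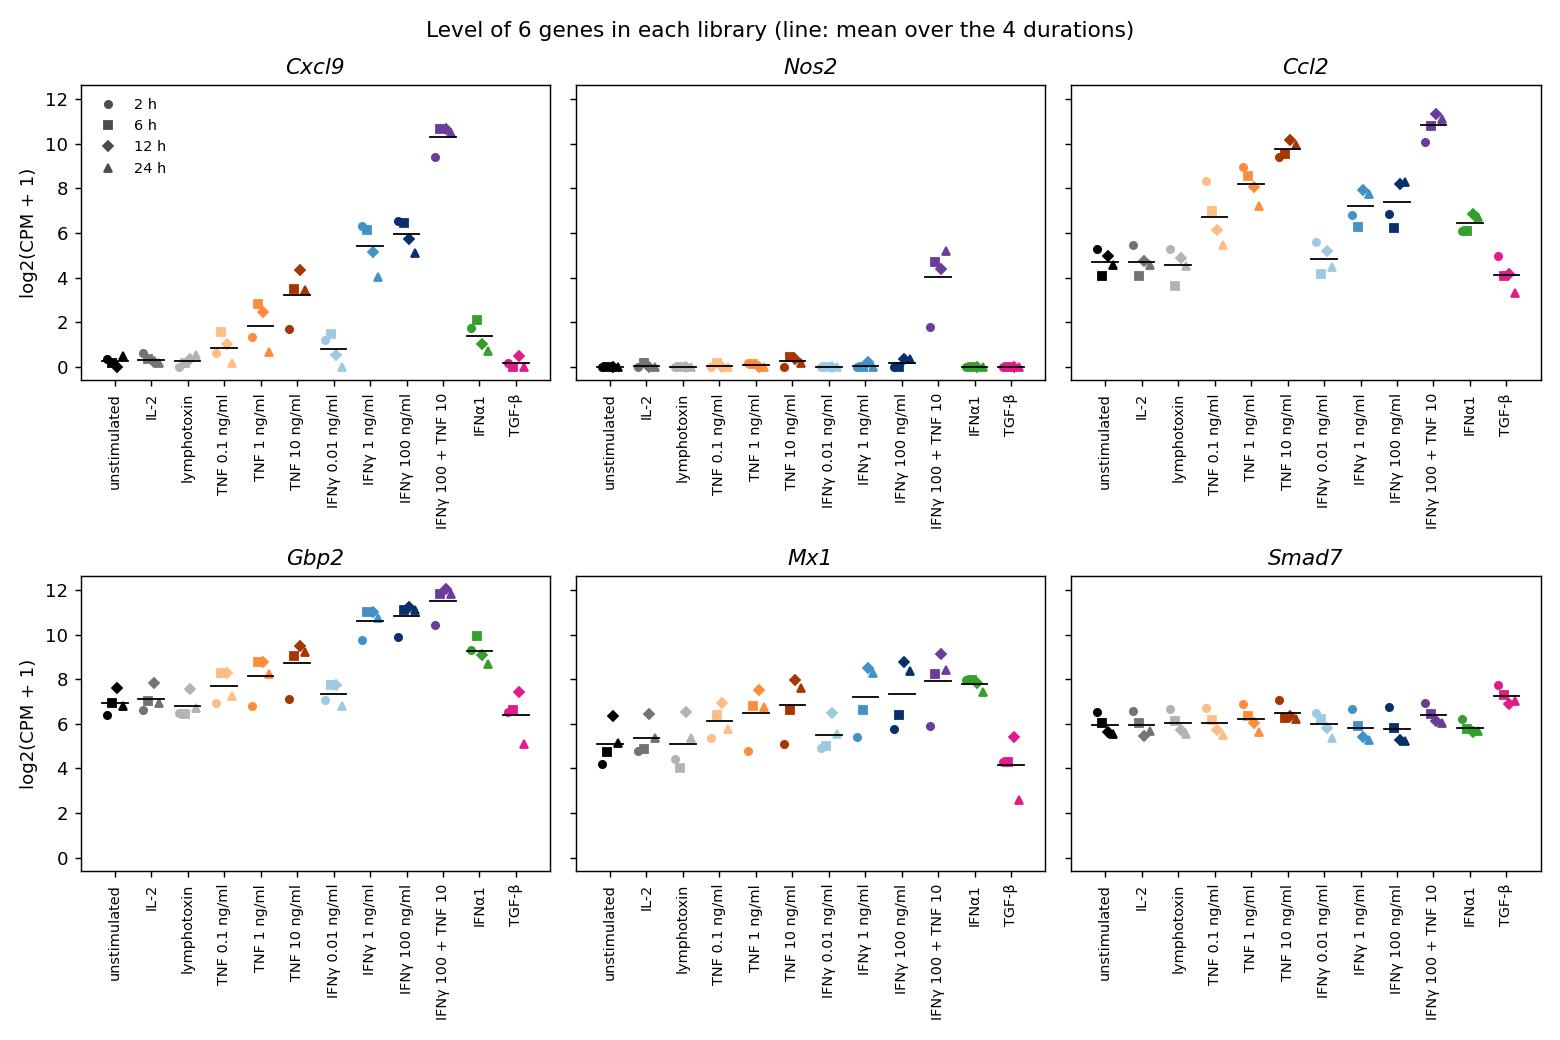
Level of 6 genes in log2(CPM + 1) in each of the 48 libraries, by stimulus, with a marker per duration and a line at the mean over the 4 durations. Cxcl9 reached 42071 counts with the combination over 4 libraries, against 1890 with IFNγ at 100 ng/ml and 298 with TNF at 10 ng/ml.

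Against IFNγ alone, the combination had higher levels of 24 of 34 NF-κB genes (29 adjusted over the list alone, median 0.84) and of 17 of 27 chemokines and cytokines (18 adjusted over the list alone, median 1.29). Nfkbia was higher by 2.94 ± 0.19, Cxcl9 by 4.44 ± 0.34, Vcam1 by 3.72 ± 0.36 and Nos2 by 6.99 ± 0.40 (4 to 680 counts). Trib2 was lower (-1.56 ± 0.24). Against TNF alone, all 19 GTPases (median 2.09) and 21 of 23 type II genes (median 2.52) were higher, with Batf2, an interferon-induced transcription factor, at 5.92 ± 0.35, Cxcl9 at 7.08 ± 0.41 and Cd274 at 2.52 ± 0.41. Ubd, a ubiquitin-like protein, had 830 counts in the combination against 3 with TNF (257-fold, 95% interval 87.5 to 1247). These 4 lists were called (adjusted p = 3.58e-55, 5.72e-16, 1.58e-40 and 1.37e-38), with an estimated correlation as well. The combination differed from IFNγ at 1697 genes, 1036 higher and 661 lower, and from TNF at 1704, 1113 higher and 591 lower. Without the 6 h, 12 h and 24 h libraries these counts were 718, 643 and 1044 (179, 184 and 350 of them lower), and 810, 786 and 950 (180, 201 and 171 lower). They were 413 and 455 (77 and 47 lower) within the 2 h and 6 h libraries, 2053 and 2274 (821 and 916 lower) within the 12 h and 24 h ones, and 1053 and 1068 (316 and 251 lower) with the compared groups alone.

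Whether the joint effect departs from the sum of the single log2 effects was tested as non-additivity. In 10 genes it did, above the sum in 8 and below it in 2. Sod2, a mitochondrial antioxidant enzyme and 1 of 34 NF-κB genes, stood 0.80 ± 0.12 above the sum, Ninj1, which takes part in plasma membrane rupture, 1.20 ± 0.17, and the small GTPase Rhob 1.11 ± 0.17. The 2 lower ones were the transcription termination factor Ttf2 (-0.43 ± 0.09) and Gm12250 (-2.58 ± 0.48), which was named after its values were seen because its name is that of a predicted gene. For Cxcl9 the departure was -1.11 ± 1.58 (adjusted p = 0.83). The GTPase list lay below the sum (median -0.87, adjusted p = 9.65e-11), with 0 of its 19 genes called by edgeR and 10 lower when adjusted over the list alone, but at adjusted p = 0.196 with an estimated correlation. Sod2 was the 1 NF-κB gene called (1 adjusted over the list alone, list median 0.05, adjusted p = 0.361). The count of 10 became 45, 0, 2 and 3 without the 2 h, 6 h, 12 h and 24 h libraries, and without the 6 h libraries Sod2 (0.62), Ninj1 (1.08), Rhob (1.07), Ttf2 (-0.37) and Gm12250 (-2.75) lost their calls. Rhob (1.14), Ttf2 (-0.46) and Gm12250 (-2.80) also lost them without the 12 h libraries, and Ttf2 (-0.42) and Gm12250 (-2.18) without those of 24 h. It was 0 within the 2 h and 6 h libraries, 94 within the 12 h and 24 h ones (27 above and 67 below the sum), 0 with the compared groups alone and 23 by DESeq2. With the compared groups alone Sod2 stood at 0.79, Ninj1 at 1.20, Rhob at 1.10, Ttf2 at -0.43 and Gm12250 at -2.58, and Ttf2 also lost its call with IL-2 as the reference (-0.34) or without a filter (-0.41).

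The lower doses of IFNγ were compared with unstimulated cells and with the highest dose. At 1 ng/ml, all 23 type II genes (median 2.79) and all 19 GTPases (median 2.72) rose, with Irf1 at 3.73 ± 0.30, Cxcl9 at 7.75 ± 0.78, Gbp10 at 6.85 ± 0.47 and Batf2 at 6.57 ± 0.47. Serpina3f was at least 41.8-fold and Ido1 at least 8.56-fold higher than in unstimulated cells, but Serpina3f was not called without the 6 h libraries (adjusted p = 0.0553) or among those of 2 h and 6 h alone. Both lists were called (adjusted p = 4.25e-45 and 1.70e-62), with an estimated correlation and adjusted over the list alone as well. In all, 1827 genes were called, 1160 higher and 667 lower, and the count became 2750, 982, 667 and 804 without the 2 h, 6 h, 12 h and 24 h libraries (1128, 217, 110 and 157 of them lower). It was 272 (24 lower) within the 2 h and 6 h libraries and 2935 (1350 lower) within the 12 h and 24 h ones. Between 100 and 1 ng/ml, 0 genes were called by edgeR and 0 by DESeq2, with 303 at an unadjusted p under 0.05 in edgeR and 18 called with the compared groups alone. Irf1 differed by 0.17 ± 0.26, Gbp10 by 0.40 ± 0.22 and Cxcl9 by 0.44 ± 0.33 between these doses, which leaves room for small differences. At 0.01 ng/ml, edgeR and DESeq2 called 0 genes, with 229 at an unadjusted p under 0.05 in edgeR and 36 called with the compared groups alone. The GTPases had a median of 0.55 (adjusted p = 2.27e-19, 0 of 19 called, also 0 adjusted over the list alone), at adjusted p = 0.0524 with an estimated correlation. Irf1 stood at 0.80 ± 0.30 (adjusted p = 1). The GTPase median was 0.86, 0.75, 0.15 and 0.15 at 2, 6, 12 and 24 h.

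At 1 ng/ml TNF, 19 of 34 NF-κB genes (23 adjusted over the list alone, median 0.49) and 11 of 27 chemokines (16 adjusted over the list alone, median 1.20) rose. Ccl2 was higher by 3.65 ± 0.52, Tnip3, an NF-κB feedback gene, by 2.95 ± 0.40, and Acod1 by 4.55 ± 0.78. Both lists were called (adjusted p = 4.99e-35 and 2.50e-15), with an estimated correlation as well. In all, 332 genes were called, 245 higher and 87 lower, and the count became 718, 43 and 76 without the 2 h, 6 h and 12 h libraries (206, 9 and 11 of them lower). It was 104 (19 lower) within the 2 h and 6 h libraries, 420 (140 lower) within the 12 h and 24 h ones and 859 (308 lower) with the compared groups alone. At 10 against 1 ng/ml, 29 genes were higher and 0 lower, including Ch25h, which makes 25-hydroxycholesterol (2.02 ± 0.39), and Tnfaip3 (1.04 ± 0.16). Of the NF-κB list, 6 of 34 were higher (17 adjusted over the list alone, median 0.31, adjusted p = 2.23e-25, called with an estimated correlation as well). This count of 29 became 132, 4, 0 and 0 without the 2 h, 6 h, 12 h and 24 h libraries, and Ch25h and Tnfaip3 lost their calls without those of 12 h (1.71 and 0.89) or 24 h (1.71 and 0.88). It was 0 within the 2 h and 6 h libraries, with Ch25h at 0.91 and Tnfaip3 at 0.61, 374 (101 lower) within the 12 h and 24 h ones, and 0 with the compared groups alone, with Ch25h at 2.07 and Tnfaip3 at 1.05. At 0.1 ng/ml TNF, 2 genes were called, Slfn2, an interferon-induced gene (1.12 ± 0.20), and Id2, an inhibitor of transcription factors (-0.80 ± 0.14). Neither was called without the 2 h (1.13 and -0.52), 6 h (0.94 and -0.97) or 12 h libraries (1.26 and -0.83), when the count was 0, nor Slfn2 without a filter (1.12). DESeq2 called 19 genes, the compared groups alone 118, the 2 h and 6 h libraries 12 and the 12 h and 24 h ones 0. The NF-κB list was higher at this dose (median 0.31, adjusted p = 2.48e-19, called with an estimated correlation as well) with 0 of 34 genes called by edgeR and 13 adjusted over the list alone. Its median was 0.55, 0.31, 0.11 and 0.15 at 2, 6, 12 and 24 h.

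IFNα1, a type I interferon, was compared with unstimulated cells and with IFNγ. All 38 type I genes rose (median 1.26), including the antiviral genes Mx1 (2.94 ± 0.48), Ifit2 (2.53 ± 0.40) and Rsad2 (2.37 ± 0.35). The GTPases (18 of 19, median 1.83), the type II list (15 of 23, median 1.41, or 1.38 with members near the floor at their bound) and MHC class I genes (20 of 24, 21 adjusted over the list alone, median 1.38) rose as well. Tnfsf10, the death ligand TRAIL, rose by 3.44 ± 0.59. These 4 lists were called (adjusted p = 1.68e-58, 2.01e-40, 1.29e-25 and 2.02e-28), with an estimated correlation as well. In all, 1131 genes were called, 754 higher and 377 lower. The count was 562 without the 6 h libraries (474 higher and 88 lower), 572 without those of 12 h (533 and 39) and 754 without those of 24 h (650 and 104). It was 492 within the 2 h and 6 h libraries (472 and 20) and 1156 within the 12 h and 24 h ones (732 and 424). Mx1 (2.67), Rsad2 (2.16) and Tnfsf10 (3.05) were not called with the compared groups alone, nor Mx1 without a duration term (2.51). The mitochondrial share of counts with IFNα1 was 1.44% at 2 h and 0.734% at 24 h, against 1.17% and 0.964% in unstimulated cells.

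IFNγ at 100 ng/ml gave higher levels than IFNα1 of Cxcl9 (5.14 ± 0.52), Batf2 (4.56 ± 0.35), Gbp10 (3.45 ± 0.29) and Irf1 (1.95 ± 0.27), and of 13 of 23 type II genes (16 adjusted over the list alone, median 1.07). Ciita, with no counts under IFNα1, was at least 17.3-fold higher. The cytokine gene Tslp was lower with IFNγ (-1.55 ± 0.32), but was not called among the 2 h and 6 h libraries alone (-1.26). The type II list was called (adjusted p = 2.47e-12), with an estimated correlation as well. The GTPase list had 14 of 19 genes higher (18 adjusted over the list alone, median 1.00, adjusted p = 5.09e-15), and its call was lost at adjusted p = 0.0994 with an estimated correlation. Of 12203 genes, 1157 were higher and 807 lower with IFNγ, 1964 in all. This count became 1041, 318 and 928 without the 6 h, 12 h and 24 h libraries (469, 111 and 412 of them lower). It was 394 (136 lower) with the compared groups alone, 172 (67 lower) within the 2 h and 6 h libraries and 3101 (1527 lower) within the 12 h and 24 h ones. The doses were in different units, so that they cannot be matched.

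TGF-β was compared with unstimulated cells. Of 45 TGF-β and SMAD targets, 18 rose and 4 fell (21 and 7 adjusted over the list alone, median 0.21). Those higher included the feedback inhibitors Smad7 (1.32 ± 0.11, adjusted p = 1.11e-11) and Skil (0.84 ± 0.11), and Timp1, an inhibitor of matrix proteases (1.14 ± 0.15). The lower ones included Id2 (-1.49 ± 0.14) and Snai2, a transcription factor of epithelial-mesenchymal transition (-0.74 ± 0.11). Outside the list, the protease inhibitor Tfpi2 rose by 4.16 ± 0.56, the elastase Mmp12 by 4.06 ± 0.61, the growth factor Fgf2 by 2.07 ± 0.20 and Vegfa by 1.05 ± 0.13, and Mrgprf (-2.87 ± 0.58) and Lrrc32, which holds latent TGF-β on cells (-2.14 ± 0.38), fell. The methyltransferase Bhmt stood at 2 counts against 34 (0.0563-fold, 95% interval 0.00656 to 0.22), and was not called without the 6 h libraries (adjusted p = 0.0714) or without a duration term (adjusted p = 0.197). In all, 1010 genes were called, 613 higher and 397 lower, and the TGF-β list was called (adjusted p = 2.03e-08), with an estimated correlation as well. The count was 542, 505 and 670 without the 6 h, 12 h and 24 h libraries (160, 150 and 263 of them lower). It was 344 (95 lower) within the 2 h and 6 h libraries and 1135 (509 lower) within the 12 h and 24 h ones. Id2 (-1.57) and Skil (0.88) were not called without a duration term. The type I interferon list had a median of -0.29 with 0 of 38 genes called by edgeR, also 0 adjusted over the list alone (adjusted p = 6.45e-06, or 0.633 with an estimated correlation). That median was -1.19 at 24 h, and 0.05, -0.06 and -0.20 at 2, 6 and 12 h.

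Lymphotoxin α1β2 and IL-2 were each compared with unstimulated cells. With lymphotoxin, edgeR and DESeq2 called 0 genes, with 195 at an unadjusted p under 0.05 in edgeR and 7 called with the compared groups alone. The NF-κB gene Relb stood at -0.10 ± 0.19. The lymphotoxin receptor gene Ltbr was measured at 86.1 ± 12.5 CPM (SD, n = 4 durations) in unstimulated cells. With IL-2, edgeR and DESeq2 called 0 genes, with 152 at an unadjusted p under 0.05 in edgeR. Cish, a target of IL-2 signalling in lymphocytes, stood at 0.20 ± 0.35. The receptor gene Il2ra had no counts in unstimulated cells, where 3 counts in a library would be 0.387 to 0.496 CPM, and Il2rb stood at 0.832 ± 0.327 CPM (SD, n = 4 durations). TNF at 10 ng/ml differed from lymphotoxin at 2222 genes, 1270 higher and 952 lower, with Ccl2 higher by 5.23 ± 0.54 and 26 of 34 NF-κB genes higher (29 adjusted over the list alone, median 0.90, adjusted p = 2.12e-43, called with an estimated correlation as well). That count was 962, 940 and 1130 without the 6 h, 12 h and 24 h libraries (286, 296 and 385 of them lower). It was 296 (70 lower) within the 2 h and 6 h libraries, 2474 (1069 lower) within the 12 h and 24 h ones and 1283 (513 lower) with the compared groups alone. These doses were 10 and 2 ng/ml.

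Time in culture was compared as 24 h against 2 h over all 12 groups, of which 11 held a cytokine for that time. The change therefore mixes time in culture with cytokine responses that grew or declined with duration. Of 45 TGF-β and SMAD targets, 26 fell and 8 rose (the same counts adjusted over the list alone, median -0.32), including the matrix genes Ctgf (-4.30 ± 0.12) and Thbs1 (-4.15 ± 0.14) and Id2 (-4.13 ± 0.08). The vasoconstrictor gene Edn1 fell as well (-4.60 ± 0.34), and the chemokine receptor gene Cxcr4 rose by 2.38 ± 0.15. Of 32 hypoxia and glycolysis genes, 23 fell and 4 rose (the same adjusted over the list alone, median -0.30), with Ldha, the lactate dehydrogenase subunit, at -0.54 ± 0.06. Of 38 type I interferon genes, 31 rose (the same adjusted over the list alone, median 0.68), with Mx1 at 1.28 ± 0.29. Over unstimulated cells of the same duration, the median of this list went from 0.14 to 1.17 with TNF at 10 ng/ml. With the combination it went from 0.77 to 1.41, with IFNα1 from 1.25 to 1.11 and with TGF-β from 0.05 to -1.19. In all, 8207 genes were called, 4247 higher and 3960 lower, of which 442 were at least 2-fold higher and 307 at least 2-fold lower. The TGF-β list was called (adjusted p = 1.87e-08), with an estimated correlation as well, while the calls of the hypoxia and type I lists (adjusted p = 0.00227 and 1.07e-05) were lost with an estimated correlation (adjusted p = 0.535 and 0.644). The index sets separate 2 h from 24 h, so that a batch cannot be told apart from time in this comparison. Its tests and errors treat the libraries of a duration as independent of one another, which the labels do not show. Within the sets, 6975 genes differed between 6 h and 2 h and 3919 between 24 h and 12 h (1855 higher and 2064 lower). Of those also called at 24 h against 2 h, 1122 of 5073 and 684 of 2890 had the opposite sign. From unstimulated and IL-2 libraries alone, 4660 genes were called, 2326 higher and 2334 lower. The mitochondrial share in unstimulated cells was 1.17% at 2 h and 0.964% at 24 h.

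Whether a response grew or declined with duration was tested as a slope per doubling of the hours, relative to unstimulated cells. In the IFNγ response at 100 ng/ml, 15 of 29 stress and amino acid supply genes rose with duration (20 adjusted over the list alone, median slope 0.19), and Ddit3, a stress transcription factor, gained 0.46 ± 0.11 per doubling. In the combination, 19 of the 29 rose (22 adjusted over the list alone, median slope 0.27), Ddit3 gaining 0.73 ± 0.11 and Trib3 0.52 ± 0.09, and the chemokine Ccl5 gained 1.66 ± 0.22. Both list calls (adjusted p = 4.32e-17 and 1.05e-18) held with an estimated correlation. With TNF, 6 of the 29 rose (10 adjusted over the list alone, median slope 0.13, adjusted p = 6.66e-10), but at adjusted p = 0.0574 with an estimated correlation. Cholesterol biosynthesis fell with duration in the combination for 12 of 22 genes (16 lower and 1 higher adjusted over the list alone, median slope -0.29, adjusted p = 2.94e-09), but at adjusted p = 0.23 with an estimated correlation. Among single genes, the cell surface gene Tenm4 fell with duration under IFNγ (-1.03 ± 0.13), Ly6c1, an interferon-inducible surface gene, rose under IFNα1 (1.13 ± 0.17), and the doublecortin-domain gene Dcdc2a fell under TNF (-0.93 ± 0.14). The mitochondrial share at 24 h was 0.693% with IFNγ, 0.513% with the combination and 0.695% with TNF, and the unstimulated library (0.964%) was the highest of the 12, above IL-2 (0.851%), TGF-β (0.844%) and lymphotoxin (0.836%) as well.

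Slopes were called for 842 genes with IFNγ, 297 with TNF, 2125 with the combination and 101 with IFNα1. Without the 24 h libraries these counts were 37, 23, 700 and 0, and without those of 2 h they were 423, 105, 858 and 15. Without the 12 h libraries the counts for IFNγ, TNF and IFNα1 were 474, 104 and 10, and without those of 6 h the count for IFNα1 was 259. Within the 2 index sets the counts were 0, 0, 259 and 1. Trib3 in the combination was called within the sets. The slopes within the sets of Tenm4 (-1.03), Ccl5 (1.77), Ddit3 (0.66 with the combination and 0.40 with IFNγ), Ly6c1 (0.96) and Dcdc2a (-0.63) kept their direction but were not called. Without the 24 h libraries the slopes of Ddit3, at 0.26 with IFNγ and 0.45 with the combination, of Trib3, at 0.43, of Ly6c1, at 1.04, and of Dcdc2a, at -0.78, were not called either, and that of Ly6c1, at 1.36, was not called without the 2 h libraries.

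**Figure D3:**
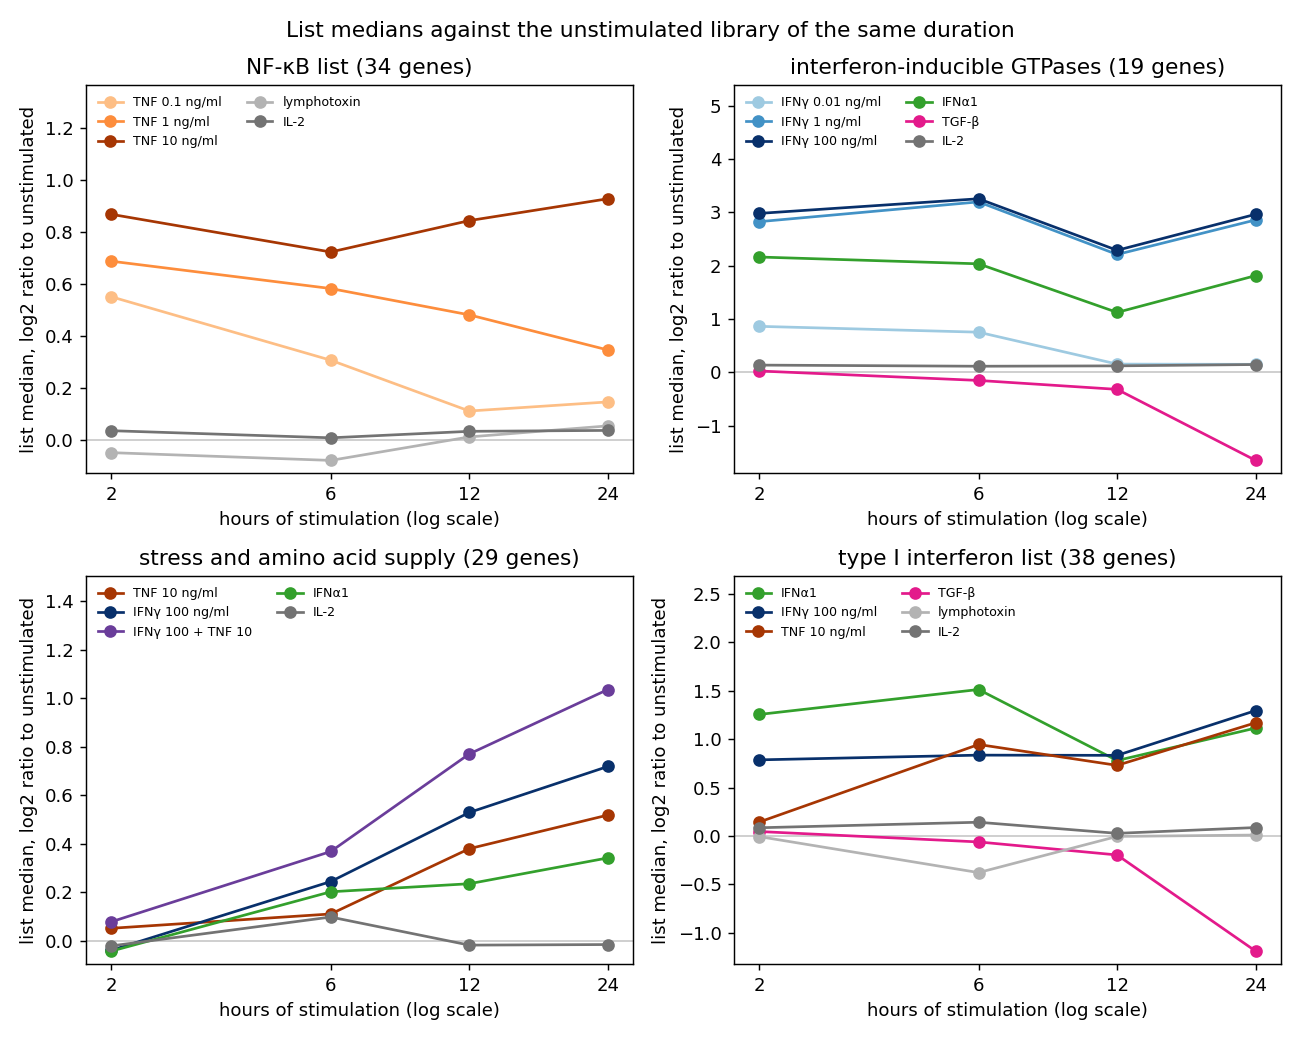
Median log2 ratio of 4 gene lists to the unstimulated library of the same duration, at 2, 6, 12 and 24 h on a log scale. Each line is a stimulus with 1 library per duration and no error. The NF-κB median with TNF at 0.1 ng/ml went from 0.55 at 2 h to 0.15 at 24 h, and the stress list median with the combination from 0.08 to 1.04.

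At single durations, the number of genes at least 2-fold apart from the unstimulated library was counted without a test. With the combination it was 371, 816, 1034 and 1402 at 2, 6, 12 and 24 h, with IFNγ at 100 ng/ml 226, 261, 416 and 703, and with TNF at 10 ng/ml 116, 293, 403 and 587. With TNF at 1 ng/ml it was 83, 224, 133 and 174, and at 0.1 ng/ml 109, 105, 15 and 36, so that the count at 2 h did not follow the dose. With TGF-β it was 124, 195, 214 and 405, and with IFNα1 264, 279, 161 and 251. IL-2 gave 13, 5, 10 and 7 and lymphotoxin 12, 6, 18 and 9, which shows the background of such pairs of libraries.

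**Figure D4:**
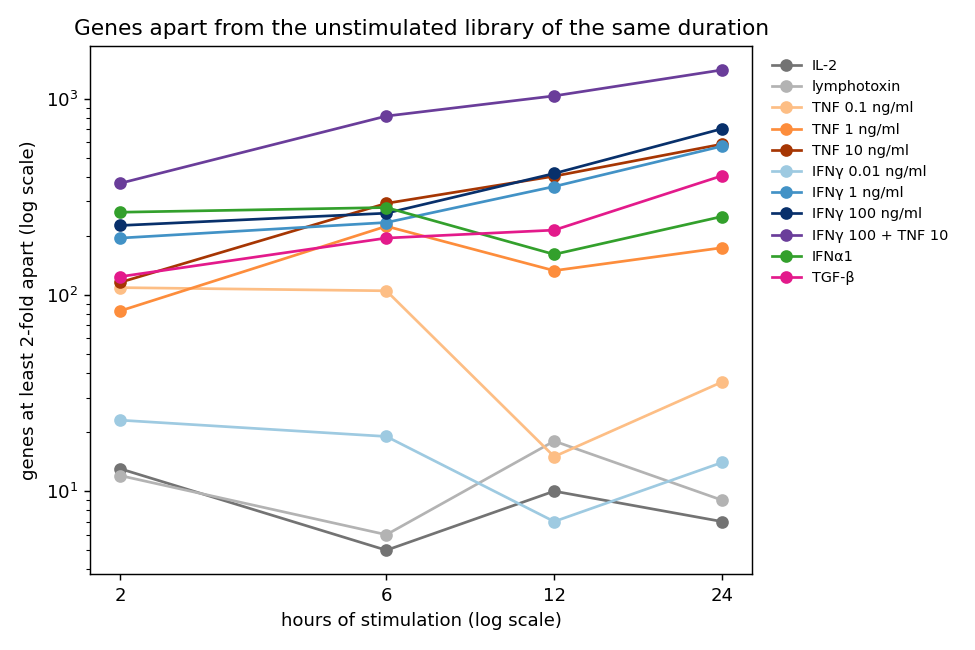
Number of genes at least 2-fold apart from the unstimulated library of the same duration (log scale) at 2, 6, 12 and 24 h (log scale), with 1 line per stimulus and 1 library per point. The combination reached 1402 genes at 24 h, while IL-2 stayed between 5 and 13.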

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

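All tests of explanations and all regroupings of libraries given here were chosen only after the results were seen. The p values of list slopes here come from camera and are not adjusted.

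Total counts and the share of the 50 highest genes were among the measures checked for a library far from the other 3 of its stimulus. Of 59 such groups, 4 had one. The chance share of about 1 in 20 is meant for replicates and does not apply here, because these libraries differ in duration. The TNF 10 ng/ml library of 6 h held 8299893 counts. At 2 h the 50 highest genes held 11.8% of the counts with IFNα1, 11.8% with TNF at 1 ng/ml and 11.4% with IFNγ at 100 ng/ml.

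A response that differs between durations was found by the test of the slope in 842 genes with IFNγ, 297 with TNF, 2125 with the combination and 101 with IFNα1. The effects of IFNγ and TNF differed with and without the other cytokine in 10 genes. The slope of the NF-κB list differed between TNF at 10 and at 0.1 ng/ml (p = 0.000147 with an estimated correlation).

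The NF-κB list median with the lowest TNF dose and the GTPase median with the lowest IFNγ dose were lower at 12 h and 24 h than at 2 h and 6 h. At 2 h the NF-κB medians followed the TNF dose (0.550, 0.687 and 0.867 at 0.1, 1 and 10 ng/ml). The type I medians did not (0.293, 0.044 and 0.142). Whether the 2 h library of the lowest TNF dose was unusual was not tested. For TNF, with late over early ratios of the NF-κB list of 1.11, 0.651 and 0.3 at 10, 1 and 0.1 ng/ml, folds compressed in the second set of index sequences are argued against by the slope, which was higher at 10 than at 0.1 ng/ml (p = 0.000147), though the late fold at 0.1 ng/ml against its early fold times 0.651 gave p = 0.0572, both with an estimated correlation. Unstimulated cells in place of the late libraries of the lowest TNF dose are argued against only weakly by their type I medians. The lower of these was 0.296, against -0.379 to 0.141 in the 8 IL-2 and lymphotoxin libraries. The lowest of those 8 strayed further than 0.296, in the other direction. The NF-κB medians of the lowest TNF dose at 12 h and 24 h, 0.111 and 0.146, argue against it as well. They lay above those 8 libraries, which stood at -0.0785 to 0.0541 on that list. A response that ends sooner at a low dose may account for the TNF pattern. The NF-κB slope also differed between 10 and 1 ng/ml (p = 3.28e-05 with an estimated correlation). That test used the same list and the same 10 ng/ml libraries, so that it cannot tell an earlier end from other causes of slopes that differ by dose. For IFNγ, the GTPase ratios were 0.842 at 100 and at 1 ng/ml and 0.186 at 0.01 ng/ml, but the same tests gave p = 0.347 and 0.0798 with an estimated correlation, so that a compression and a response that ends sooner both stay open.

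The stress and amino acid supply list rose with duration under IFNγ and the combination. Its median over unstimulated cells was also higher at 24 h than at 2 h with other stimuli. It went from 0.05 to 0.63 with IFNγ at 1 ng/ml, from 0.05 to 0.52 and -0.02 to 0.27 with TNF at 10 and 1 ng/ml, and from -0.04 to 0.34 with IFNα1. With lymphotoxin it went from 0.05 to -0.02, and with TGF-β from -0.04 to -0.03. A step between the sets of index sequences is argued against as the whole cause by the slopes within the sets (p = 0.0363 with IFNγ and 0.0417 with the combination, with an estimated correlation). Medium used up by all cultures alike would cancel in these slopes, which are relative to unstimulated cells, so that it was not put to a real test. The change of the list median from 2 h to 24 h was 0.0532 with IL-2 and 0.664 with IFNγ. These values do not bear on medium use that differed between cultures, which was not tested. A late response to IFNγ beyond that to type I interferon could be a candidate explanation, but the slope of IFNγ minus that of IFNα1 gave p = 0.0930 and leaves it open, while that of the combination, which also holds TNF, minus that of IFNα1 gave p = 0.0164, both with an estimated correlation. Whether the mitochondrial share, at 24 h highest in the unstimulated library of the 12, has a part in it was not tested.

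The 8 libraries of a comparison can be split in 32 ways that a fit with a duration term can tell from duration. The libraries are matched by duration, and 8 of these splits, the real one included, keep that match, which is too few for a share under 0.05. With the compared groups alone, the real split and the highest of the other 7 gave 1474 and 0 genes for IFNγ at 100 ng/ml, 1267 and 0 at 1 ng/ml and 36 and 16 at 0.01 ng/ml. They gave 1543 and 0 for TNF at 10 ng/ml, 859 and 0 at 1 ng/ml, 118 and 0 at 0.1 ng/ml, 2024 and 0 for the combination, 799 and 0 for IFNα1, 829 and 0 for TGF-β, and 7 and 60 for lymphotoxin. They gave 1053 and 0 for the combination against IFNγ, 1068 and 0 against TNF, 18 and 209 for IFNγ at 100 against 1 ng/ml, 394 and 0 for IFNγ against IFNα1, and 1283 and 0 for TNF against lymphotoxin. Among all 32 splits, most of which mix durations, 5 gave as many genes as the real one for IFNγ at 0.01 ng/ml, 8 for lymphotoxin, 4 for IFNγ at 100 against 1 ng/ml, 3 for IFNγ against IFNα1 (highest other 1087) and 1, the real one, for the others with a real count above 0. For IL-2 (highest other 34) and TNF at 10 against 1 ng/ml (652), the real count of this fit was 0, so that all 32 splits had to give as many and the splits decide nothing. The same holds for the 100 draws of non-additivity, where the real count of the fit on 16 libraries was 0 and the highest other 678. For culture time, 1 of 100 draws that keep each stimulus together, the real one (6984, highest other 5050), gave as many genes. These draws treat the libraries of a duration as independent of one another, which the labels do not show. They therefore cannot exclude chance differences between harvests of different durations, nor a step between the index sets.

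For the slopes, 4 of 25 regroupings gave as many genes with IFNγ (842, highest other 2383), 5 with TNF (297, 1634), 5 with the combination (2125, 4103) and 8 with IFNα1 (101, 1016). Only 8 splits keep the durations matched, too few for a share under 0.05. In all 4 cases the highest count was that of the split that exchanges the labels at 12 h and 24 h, which follows the index sets and turns a mean difference between the stimuli into a slope, so that its high counts follow from how it is built. Within the sets, 0, 0, 259 and 1 slopes were called.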

How the results depend on the processing

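The counts within the sets of index sequences and the counts at 6 h against 2 h and at 24 h against 12 h were chosen after seeing the data, and all other alternatives before the data were examined. With DESeq2 size factors all 24 counts stayed within 1.5 times the reported ones, and 0 of the lists called in both changed direction. No paired analysis was possible by replicate number because the labels name durations and no replicates, and libraries of the same duration are matched by the duration term of the reported fit. The cause of the changes was not tested, except that leaving out libraries or adding genes changes the number of libraries or genes by construction. A fit of the compared groups alone also replaces the spread pooled over all groups by that of the groups compared.

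Leaving out 1 duration gave 1041 to 3442 genes for IFNγ at 100 ng/ml, 667 to 2750 at 1 ng/ml, 794 to 2645 for TNF at 10 ng/ml, 43 to 718 at 1 ng/ml, 0 to 2 at 0.1 ng/ml, 562 to 1363 for IFNα1 and 505 to 1206 for TGF-β. It gave 643 to 2342 for the combination against IFNγ, 786 to 2461 against TNF, 0 to 132 for TNF at 10 against 1 ng/ml, 318 to 2793 for IFNγ against IFNα1, 940 to 2816 for TNF against lymphotoxin and 0 to 45 for non-additivity. The slopes gave 37 to 1001 with IFNγ, 23 to 415 with TNF, 700 to 2266 with the combination and 0 to 259 with IFNα1.

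Without a duration term, the counts were 615 for IFNγ at 100 ng/ml, 355 at 1 ng/ml, 355 for TNF at 10 ng/ml, 38 at 1 ng/ml, 0 at 0.1 ng/ml, 2388 for the combination, 175 for IFNα1, 241 for TGF-β, 350 and 426 for the combination against IFNγ and TNF, 1 for TNF at 10 against 1 ng/ml, 134 for IFNγ against IFNα1, 383 for TNF against lymphotoxin and 0 for non-additivity. With the compared groups alone they were 1474 for IFNγ at 100 and 36 at 0.01 ng/ml, 859 and 118 for TNF at 1 and 0.1 ng/ml, 2024 for the combination, 7 for lymphotoxin, 1053 and 1068 for the combination against IFNγ and TNF, 18 for IFNγ at 100 against 1 ng/ml, 0 for TNF at 10 against 1 ng/ml, 394 for IFNγ against IFNα1, 1283 for TNF against lymphotoxin and 0 for non-additivity.

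Within the 2 h and 6 h libraries, the counts were 446 and 272 for IFNγ at 100 and 1 ng/ml, 283, 104 and 12 for TNF at 10, 1 and 0.1 ng/ml, 1853 for the combination, 492 for IFNα1, 344 for TGF-β, 413 and 455 for the combination against IFNγ and TNF, 0 for TNF at 10 against 1 ng/ml, 172 for IFNγ against IFNα1, 296 for TNF against lymphotoxin and 0 for non-additivity. Within those of 12 h and 24 h, the ones that moved were 2935 for IFNγ at 1 ng/ml, 0 for TNF at 0.1 ng/ml, 374 for TNF at 10 against 1 ng/ml, 3101 for IFNγ against IFNα1 and 94 for non-additivity. Slopes within the sets were called for 0 genes with IFNγ, 0 with TNF, 259 with the combination and 1 with IFNα1.

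Without a filter, 201 genes were called for TNF at 1 ng/ml, 1 at 0.1 ng/ml, 14 for TNF at 10 against 1 ng/ml, 1196 for IFNγ against IFNα1, and 529, 189 and 50 for the slopes with IFNγ, TNF and IFNα1. DESeq2 called 19 genes for TNF at 0.1 ng/ml, 23 for non-additivity and 175 for the IFNα1 slope. With IL-2 as the reference, 16 were called for non-additivity and 53 for the IFNα1 slope, and on a linear scale of hours 192 for the TNF slope and 50 for the IFNα1 slope. Culture time gave 4660 genes from unstimulated and IL-2 libraries and 3919 for 24 h against 12 h. An estimated correlation left 70 of the 210 list calls, and a log2 limit of 2 left 2701 of the 10902 values at single durations. Of 1404 values of the printed genes under alternatives, 1306 kept their side of the threshold, 98 lost a call and 0 changed sign. These genes were chosen with preference for stable calls, so these counts do not describe genes in general. At these depths, 3 counts in a library are 0.310 to 0.534 CPM, and differences below that level cannot be seen.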

Other observations

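The tests of the TGF-β pattern given here were chosen only after the result was seen.

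Unstimulated NMM cells had no counts for the pigmentation genes Tyr, Dct and Mlana or for Sox10, a transcription factor of the melanocyte lineage, and 12 counts for Pmel over 4 libraries. Mitf stood at 6.31 ± 1.25 CPM (SD, n = 4 durations). The receptor tyrosine kinase gene Axl stood at 1888 ± 68.9 CPM, the matrix gene Fn1 at 6163 ± 589 CPM and Spp1, which encodes osteopontin, at 4660 ± 478 CPM. Interferon-stimulated genes were measured without any cytokine, Rsad2 at 564 ± 286 CPM and Isg15 at 423 ± 96.8 CPM. Of 26 melanocyte genes in the file, 9 could be tested, and with the combination 1 was higher and 2 lower (1 and 1 adjusted over the list alone, median -0.16, adjusted p = 0.868). Of 18 dedifferentiation genes, 8 were higher and 3 lower (the same adjusted over the list alone, median 0.23, adjusted p = 0.112), with Axl at 0.32 ± 0.05, which was not called with the compared groups alone (0.33, adjusted p = 0.0633).

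With the combination, 20 of 31 cytokine receptor and signalling genes rose and 1 fell (the same adjusted over the list alone, median 0.43, adjusted p = 6.20e-09, called with an estimated correlation as well), including the kinase Jak2 (1.48 ± 0.12) and the transcription factor Stat3 (1.97 ± 0.26). Of 30 immediate early genes, 17 rose and 4 fell (18 and 5 adjusted over the list alone, median 0.68, adjusted p = 9.54e-06, or adjusted p = 0.116 with an estimated correlation), with Atf3 at 2.47 ± 0.21 and Nr4a1 at -1.37 ± 0.22. Of 32 hypoxia and glycolysis genes, 6 were higher and 18 lower (the same adjusted over the list alone, median -0.27, adjusted p = 0.0769). Of 42 cell cycle genes, 7 were higher and 15 lower (8 and 15 adjusted over the list alone, median -0.04, adjusted p = 0.343), and of 20 genes of the unfolded protein response 8 were higher and 1 lower (the same adjusted over the list alone, median 0.21, adjusted p = 0.0596). Of 8 fibroblast markers, 1 was higher and 2 lower (the same adjusted over the list alone, median -0.23, adjusted p = 0.592). Too few markers of T and NK cells (1, Lck, at 1.89 ± 0.24), macrophages (2, Mrc1 at 2.78 ± 0.32 and Cd14 at -0.52 ± 0.15) and endothelium (3, with Cdh5 at 0.93 ± 0.26 and Flt1 at 0.79 ± 0.24) passed the filter for a list test. Cd14 lost its call without the 6 h (-0.40) or 12 h (-0.39) libraries, Flt1 without those of 6 h (0.58) or 12 h (0.71) and Cdh5 without those of 12 h (0.70), and none of the 3 was called with the compared groups alone (-0.53, 0.77 and 0.89) or without a duration term (-0.48, 0.83 and 0.97). Nr4a1 was not called among the 2 h and 6 h libraries alone (-1.04) or without a duration term (-1.15). Cd14 (-0.46) and Cdh5 (0.37) were not called among the 2 h and 6 h libraries alone either, nor Flt1 (0.33) among those of 12 h and 24 h. The mitochondrial share of counts was 0.513% at 24 h in these libraries.

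With TGF-β, the type I interferon list had a median of -1.19 at 24 h, below the lowest of the 8 IL-2 and lymphotoxin libraries (-0.379). A high level in the unstimulated 24 h library is argued against by the median of -1.33 against the IL-2 library of 24 h. A mislabelled library is argued against because 95.6% of 406 genes higher with TGF-β at the other durations were higher at 24 h too. Fluctuation of the basal level between libraries stays open, as the pattern stands at 1 duration (-1.19). A response that builds with duration may be an explanation as well, but without the 24 h libraries the slope of the list gave p = 0.543 with an estimated correlation, not adjusted, which leaves it open.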
